A study of Caenorhabditis elegans with 2 samples.

How the data were processed

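The samples were 2 biological replicates of a transcription factor ChIP-seq experiment on eGFP-tagged NHR-23 in whole L2 larvae, which form 1 group, per the labels. The labels give nhr-23 as the antibody and the eGFP fusion as the target, and they do not say whether the antibody bound the tag or NHR-23 itself. With an antibody to NHR-23 itself, untagged protein would be precipitated too. The deposited files were peak lists in narrowPeak format on 2 assemblies, ce11 and ce10. Each replicate had a relaxed list of peaks and background, meant as input for an analysis of the irreproducible discovery rate (IDR), and the series had a relaxed list of the pooled replicates and a list of reproducible peaks (the optimal IDR list). Per the deposited description files, the relaxed lists came from the alignments of 1 or both replicates with the alignment of a control, and the reproducible list from the pooled and replicate lists. The peak caller, aligner, their versions and the thresholds are not given in the sources used here.

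The deposited signal of each peak is the authors' value from their caller on a scale that is not given, and was used only to describe and rank peaks within a list. The deposited −log10 of the q-value saturates at the top of each list (lowest q 0.0133 in the reproducible list), so it was not used to rank. Peak lists hold no read counts, so depth is unknown and no interval that needs depth is given. Intervals on shares of peaks or windows are 95% Wilson intervals and cover counting error only. The reproducible list held the strongest peaks of the pooled list (105 of 105 on ce11, 76 of 76 on ce10), so membership of a peak does not require a strong peak in each replicate. The relaxed lists include background by design.

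Peak positions were annotated on ce11 with the Ensembl release 115 annotation of WBcel235, and sequence came from the RefSeq assembly of the same build. The lists on ce10 were used for counts and for overlap among themselves, and no coordinates were converted. A gene was called bound when a summit lay within 1000 bp of an annotated transcript start, over 19973 protein-coding genes. Replicate overlap and promoter share were tested against 1000 circular shifts along each chromosome, 1-sided. On ce10, the end of the last listed peak stood in for the chromosome length. The 20 gene lists were compared with all other protein-coding genes by 2-sided Fisher's exact tests with Benjamini-Hochberg adjustment over lists. Symbols that matched no protein-coding gene (pqn-47, lpd-1 and the microRNA genes let-7, lin-4, mir-48, mir-84 and mir-241) were left out. Sequence sites were counted in windows of 75 bp either side of summits and in windows centred 1000 bp to each side, leaving out flanks that met another summit's window of the same list, and tested by Fisher's exact test, over 2080 hexamers in the screen with Benjamini-Hochberg adjustment.

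The gene lists, tests, alternatives and the rule for named genes were set before the data were examined. The rule took the gene with the nearest start for each of the 25 strongest reproducible peaks, up to 6 bound members of each list in order of signal, and nhr-23, unc-119, lin-42 and nhr-25. The alternatives were other windows, numbers of peaks, overlap rules, background sets, nearest genes, the stronger peaks alone, each replicate alone, circular shifts in place of Fisher's test and the assembly ce10. Random windows of the same GC content as control were drawn 10 per summit within 1 percentage point of GC, over 2000 bp from pooled peaks and from the 3000 strongest peaks of each replicate.

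All calculations used python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The functions were tested on simulated data, 20 times each, with 200 shifts per set where shifts were used. For the promoter share, 40 peaks planted at starts among 105 were called in 20 of 20 sets, and 1 of 20 random sets was called. For the replicate overlap, 40 planted shared peaks among 1000 gave a mean of 41.5, with 2.01 by chance. For the gene lists over 19973 genes, a list with 5 planted members was called in 20 of 20 sets, and 1 other list was called over all 20 sets. For RGGTCA, planting it in 30% of 105 windows was called in 20 of 20 sets and 0 of 20 sets without planting were called. In the screen of 2080 hexamers a planted hexamer was called in 20 of 20 sets, with a mean of 0.05 other hexamers. The simulated windows lay at random positions, while real reproducible summits had more G and C than flanks (44.7% and 37.4%). The rates of false calls for RGGTCA and hexamers therefore may not carry over. Planting in 30% does not show the power to find a difference as small as that observed for RGGTCA (13.3% and 8.65%). Nor do 40 planted peaks show it for the observed promoter share (47.6%, with 41.3% by shift). For the gene lists, 5 planted members do not show the power to call a list with 3 or fewer bound. A control library is named in the sources for the lists, and it was not analysed here.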

Results

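Chromatin immunoprecipitation followed by sequencing was carried out on whole L2 larvae of Caenorhabditis elegans that carry an eGFP-tagged copy of nhr-23. NHR-23 is a nuclear hormone receptor of the ROR family and a regulator of molting. The animals were of mixed sex and came from a strain with an integrated transgene (wgIs43) in an unc-119 mutant background. The data are 1 group of 2 biological replicates with no second condition, so the questions are where peaks lay, at which genes and sequences, and whether both replicates marked the same positions. Only peak lists were analysed, read depth is unknown, and each peak's signal is the authors' own value on a scale that is not given, used here to describe and rank peaks within a list. Coordinates are on ce11.

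The peaks that the authors' pipeline retained as reproducible numbered 105, and the highest lay at elt-1, which encodes a GATA transcription factor required for epidermal fate. The strongest peak (chromosome IV, 9615453 to 9615912) had its summit in an intron of elt-1 (WBGene00001249) and a signal of 557.7, where the strongest peak outside that locus had 139.5. It ranked 1 in each replicate, with 216.1 in replicate 1 and 338.3 in replicate 2, where the strongest peaks elsewhere in each list had 54.3 and 83.4. In all, 5 reproducible peaks had summits within 4733 bp at elt-1, between positions 9613391 and 9618124, in the upstream intergenic DNA and the introns. Matched within 100 bp, the weakest replicate support among these 5 was that of the peak at 9617580, which ranked 8 in replicate 2 and 8788 in replicate 1. Replicate 1 also had a stronger peak outside that distance, at 9617308, which ranked 23.

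**Figure D1:**
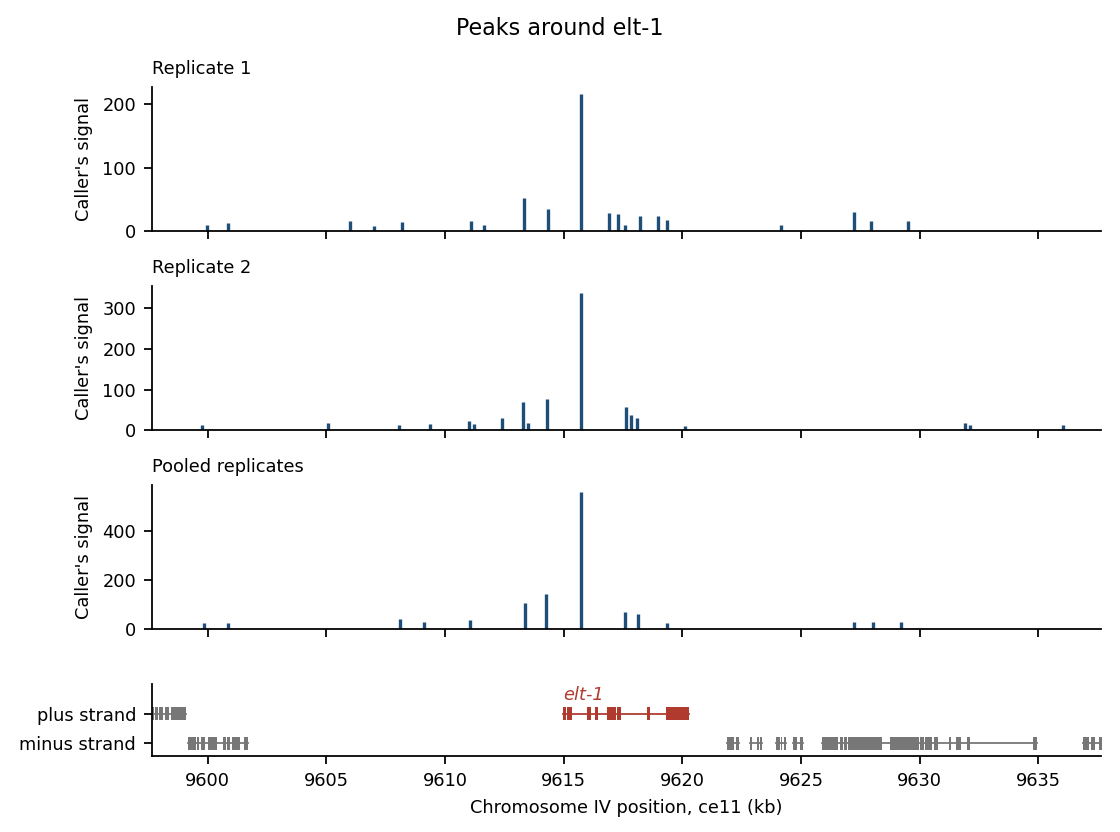
Peaks within 20 kb either side of the middle of elt-1 on chromosome IV (ce11), each drawn as a line at its summit position in kb with the caller's signal as its height, for replicate 1, replicate 2 and the pooled replicates, above the exons of protein-coding genes by strand. The tallest line in each panel, 216.1, 338.3 and 557.7, stands in an intron of elt-1, and signals are not on one scale between panels.

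The remaining strongest peaks lay at genes of varied function. Second among loci was an intergenic site 1340 bp upstream of R02D5.1 (chromosome V, 14506819 to 14507003, signal 139.5), which ranked 2 in each replicate. The peak at fasn-1, the fatty acid synthase gene, lay in an intron 439 bp downstream of a transcript start (chromosome I, 8986001 to 8986143, signal 119.5) and ranked 4 and 5 in replicates 1 and 2. A second GATA factor gene, egl-18, which acts in the seam cells of the epidermis, had intronic peaks at 1911560 (signal 98.4) and 1915095 (signal 67.2) on chromosome IV. Other nearest genes among the 25 strongest peaks were the chemoreceptor gene srw-85, scd-1 with intronic peaks at signals 94.6 and 58.5, F53E4.1, the patched-related ptr-23 (signal 82.4, intron), T24B8.4, the cytochrome P450 gene cyp-14A5, pot-3, mtm-3, the calcium channel subunit gene ccb-2, the ribosomal protein gene rpl-3, unc-53 and the protein kinase A gene kin-1. The nuclear hormone receptor genes nhr-17, nhr-168 and nhr-71 were also among them, with signals of 69.6, 60.2 and 56.9. Of these 25 peaks, 23 had a summit within 100 bp of one of the 1000 strongest peaks of both replicates. The exceptions were the elt-1 peak at 9617580 and the pot-3 peak, which ranked 9 in replicate 1 and 4116 in replicate 2.

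The 2 replicates shared few of their strong positions, though far more than chance. Of the 1000 strongest peaks of replicate 1, 68 (6.80%) had a summit within 100 bp of one of the 1000 strongest of replicate 2, against a mean of 2.06 and a maximum of 8 over 1000 circular shifts of replicate 2 along the chromosomes (one-sided permutation p = 0.001, the smallest these shifts can give). Of the 100 strongest of each, 21 were shared, against a mean of 0.02 by shift (p = 0.001, one-sided permutation). These 68 positions are called the shared strong peaks. Replicate 1 listed 30000 peaks with a median width of 296 bp and replicate 2 listed 14654 with a median width of 584 bp, so ranks in the 2 lists do not show equal strength. The 30000 of replicate 1 was the same on both assemblies, and a limit on the length of that list is not excluded. Of them, 44 peaks of replicate 1 and 53 of replicate 2 had a q-value of 0.05 or less.

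**Figure D2:**
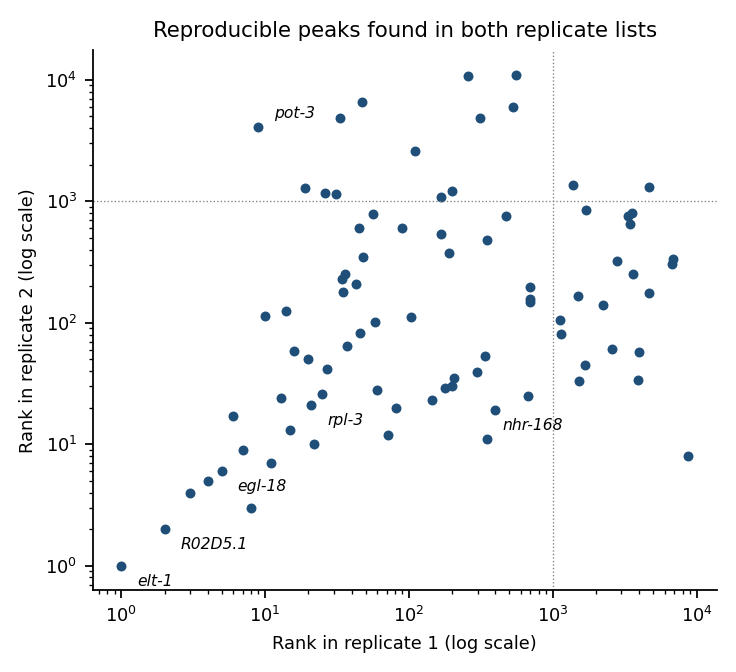
Rank by signal in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale) of the 84 reproducible peaks with a summit within 100 bp of a peak in both replicate lists, with some nearest genes named and dotted lines at rank 1000. The elt-1 peak ranks 1 in each replicate, and 50 of the 105 reproducible peaks lie inside the dotted lines.

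Most reproducible peaks could be found in each replicate, but not all in both. A replicate peak lay within 100 bp of 93 of 105 summits in replicate 1 (88.6%, 95% Wilson interval 81.1 to 93.3) and of 96 in replicate 2 (91.4%, 84.5 to 95.4), where shifted positions gave 5.98% and 2.95%. The reproducible peaks were the strongest called on the pooled reads of these same replicates, so that difference from shifted positions was largely fixed beforehand and is no independent test. By the 100 bp rule both lists held 84 of them, 21 were in only 1 list, and 50 were among the 1000 strongest of both. Overlap of 1 bp in place of summit distance found more, 96.2% in replicate 1 and 98.1% in replicate 2. The median rank of the matching peak was 158 in replicate 1 and 132 in replicate 2. The reproducible list was identical to the 105 strongest peaks of the pooled list, and 50 of the 105 had a q-value of 0.05 or less, with 0.143 as the highest. On the older assembly ce10 the same kind of list held 76 peaks.

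By annotation, 54 of the 105 summits were intergenic, 36 lay in introns, 10 in coding exons and 5 in 5′ untranslated regions of protein-coding genes. These are 51.4%, 34.3%, 9.52% and 4.76%, where 10 sets of shifted positions gave 37.2%, 33.0%, 24.7% and 1.52%, and the differences were not tested. Transcript starts of protein-coding genes lay within 1000 bp of 50 summits (47.6%, 95% Wilson interval 38.3 to 57.1), against a mean of 41.3% with an SD of 4.74 over shifted positions (one-sided permutation p = 0.102). The share thus did not pass the test, and it moved with the replicate used. The 105 strongest peaks of replicate 1 alone gave 52.4% (one-sided permutation p = 0.022) and those of replicate 2 alone 35.2% (p = 0.910, same permutation test).

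Genes with a start within 1000 bp of a reproducible summit numbered 54 of 19973 protein-coding genes, and 1 of the 20 gene lists fixed beforehand had more of them than other genes did. Ribosomal protein genes had 3 of 79 members bound, with an odds ratio of 15.4 (two-sided Fisher's exact test, p = 0.00128, Benjamini-Hochberg adjusted p = 0.0256 over 20 lists). These were rpl-3 (signal 61.5, 292 bp upstream), rpl-15 (44.9, 342 bp upstream) and rpl-35 (42.2, 437 bp upstream). Their q-values were 0.0133, 0.0963 and 0.115, so those of rpl-15 and rpl-35 were above 0.05. The 3 ranked 21, 31 and 1532 in replicate 1 and 21, 1138 and 33 in replicate 2, and ranks in the 2 lists do not show equal strength. The list did not pass with the 105 strongest peaks of replicate 1 alone (odds ratio 8.88, adjusted p = 0.157, exact test) or of replicate 2 alone (14.3, adjusted p = 0.0990, exact test). Nor did it pass in the stronger 52 reproducible peaks (14.2, adjusted p = 0.363, exact test) or with a 2000 bp window (8.88, adjusted p = 0.0564, exact test).

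Nuclear hormone receptor genes had 3 of 274 members bound (odds ratio 4.26, Fisher's exact test adjusted p = 0.221), namely nhr-168 in its 5′ untranslated region, and nhr-175 and nhr-155 at 118 and 196 bp upstream. Epidermal regulators had elt-1 alone of 17 (odds ratio 23.5, adjusted p = 0.221, exact test), since the egl-18 peaks lay more than 1000 bp from its annotated starts. When each summit was given to the gene with the nearest start at any distance, 4 lists passed. By Fisher's exact test they were nuclear hormone receptors (6 of 274, adjusted p = 0.0291), epidermal regulators (elt-1 and egl-18, 2 of 17, adjusted p = 0.0291), fatty acid genes (fasn-1 and the acetyl-CoA carboxylase gene pod-2, 2 of 21, adjusted p = 0.0295) and ribosomal protein genes (adjusted p = 0.0317). Some of these summits were distant, such as 3958 bp from nhr-17 and 5414 bp from pod-2. The test takes no account of the space around each gene, and no circular shifts were run under this rule. Within 1000 bp, 1 member each was bound in the lists of fatty acid genes (fasn-1 of 21, odds ratio 18.8), heat shock genes (hsp-3 of 20, odds ratio 19.8), hedgehog-related genes (grd-13 of 59, odds ratio 6.46) and cuticle collagens (col-187 of 176, odds ratio 2.13), and none of the 4 passed the exact test. The hsp-3 and col-187 peaks had no counterpart within 100 bp in replicate 2. Their q-values (0.0977 and 0.0949) and those of nhr-175 and nhr-155 (0.0826 and 0.118) were above 0.05, while those of nhr-168, fasn-1 and grd-13 were not.

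No bound member was found in the other 13 lists, which hold the molting genes (31), heterochronic and molting-timer genes (18), furrow collagens (6), cuticle enzymes and apical matrix genes (56), patched-related genes (29), astacin and ADAMTS proteases (42), vacuolar ATPase genes (21), histone genes (50), and genes of the intestine (24), body muscle (23), neurons (122), germline (27) and sperm (71). Neither lin-42, the period homologue, nor nhr-25 had a reproducible peak within 1000 bp of a start. The 105 strongest peaks of replicate 1 alone did reach the molting-timer genes lin-42, nhr-23 and kin-20 (3 of 18, adjusted p = 0.000407, Fisher's exact test) and the molting genes lin-42 and nhr-23 (2 of 31, adjusted p = 0.0390, exact test), while those of replicate 2 alone reached 0 members of either list. Without nhr-23, the gene carried in extra copies, the molting genes no longer passed (1 of 30, adjusted p = 0.280, exact test) and the molting-timer genes did (2 of 17, adjusted p = 0.0234, exact test). At the 68 shared strong peaks, 23 genes were bound and 0 lists passed after adjustment by Fisher's exact test, with 2 at an unadjusted p under 0.05. By the exact test those 2 rested on elt-1 (1 of 17, odds ratio 56.6, adjusted p = 0.239) and fasn-1 (1 of 21, odds ratio 45.3, adjusted p = 0.239), and rpl-3 and nhr-168 were the other members of any list.

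RGGTCA, the hexamer recognised by ROR-family receptors, was not found more often under the summits by the test. It occurred within 75 bp of 14 of 105 reproducible summits (13.3%, 95% Wilson interval 8.11 to 21.1) and in 18 of 208 windows centred 1000 bp to either side (8.65%, 5.54 to 13.3), an odds ratio of 1.62 (two-sided Fisher's exact test, p = 0.236). At the shared strong peaks it occurred in 7 of 68 summit windows and 9 of 132 flanks (odds ratio 1.57, p = 0.417, same exact test). There, windows of 150 bp either side gave an odds ratio of 3.30 (exact test p = 0.00344) and windows of 50 bp gave 0.715 (p = 0.753). The longer TRGGTCA was in 2 of 105 reproducible summit windows and 7 of 208 flanks.

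The hexamers that stood out without any being named beforehand included 2 that hold GATA, as the GATA-factor site does. These 2, AGATAA and GATAAG, overlap, so 1 site can count for both and they are not independent. Among 2080 hexamers, each counted with its reverse complement, 6 were more frequent at shared strong summits than in flanks after adjustment and 1, AAAATT, was less frequent. CTTATC, whose reverse complement is GATAAG, was in 18 of 68 summit windows (26.5%) and 6 of 132 flanks (4.55%), an odds ratio of 7.56 (Fisher's exact test, adjusted p = 0.00909). AGATAA was in 26 of 68 (38.2%) and 17 of 132 (12.9%), an odds ratio of 4.19 (adjusted p = 0.0289, exact test). The others were ATCTCC, ACCATC, AAGATG and ATCTTG, with odds ratios of 7.44, 28.1, 6.46 and 7.19. At the reproducible peaks 29 hexamers were more frequent and 18 less frequent (23 and 3 against windows of the same GC content). Of the 29, 2 hold GATA, and of the 23, 5 do. CTTATC was in 26 of 105 windows against 10 of 208 flanks (odds ratio 6.52) and AGATAA in 29 against 18 (odds ratio 4.03). Hexamers without GATA were as high against flanks, such as GATCGA (21 against 7, odds ratio 7.18) and GGGAGA (21 against 8, odds ratio 6.25). Against windows of the same GC content CTTATC and AGATAA gave 5.53 and 5.43, and GATCGA and GGGAGA 3.67 and 3.16. Without the peaks within 20 kb of elt-1 the odds ratios of CTTATC and AGATAA at shared strong peaks were 6.67 and 3.85. Their adjusted p-values, 0.0589 and 0.0786 by the exact test, no longer passed. The 3 more frequent hexamers that still passed there do not hold GATA. They were AAGATG and ATCTCC (odds ratio 8.44 and adjusted p = 0.00435 for each, exact test) and ACCATC (23.1, adjusted p = 0.0475, exact test).

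**Figure D3:**
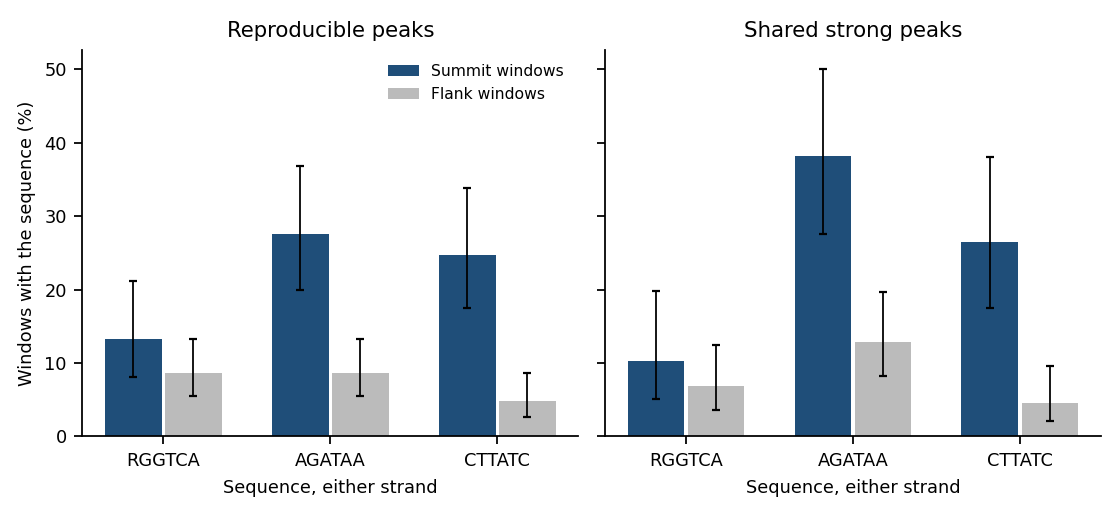
Percent of windows of 75 bp either side that hold RGGTCA, AGATAA or CTTATC on either strand, at summits (dark bars) and in flanks 1000 bp away (grey bars), for reproducible and shared strong peaks, with 95% Wilson intervals. CTTATC reaches 26.5% at shared strong summits and 4.55% in their flanks, while the intervals of RGGTCA overlap.

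Peak density at the genes carried in extra copies served as a check of the strain. Within 20 kb either side of the middle of nhr-23 (WBGene00003622, chromosome I, 7214745 to 7221299), replicate 1 listed 25 peaks, which put the window at the 99.5th percentile of windows centred on protein-coding genes, and replicate 2 listed 8, at the 73.9th. The mean percentile was 86.7 ± 18.1 (SD, n = 2). For unc-119 (chromosome III, 10902641 to 10908935) it was 41.2 ± 6.44 (SD, n = 2), with 12 and 5 peaks. The best peak within 1000 bp of an nhr-23 start ranked 62 in replicate 1, 249 in replicate 2 and 525 in the pooled list. Extra copies can raise the reads at a locus without binding, so peaks at nhr-23 are not read as binding here. At unc-119, however, the peak numbers equalled the median of genes in each replicate, so no such rise was seen there. Whether the control alignment corrected for extra copies is not known.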

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

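The peaks below the reproducible threshold are the 3805 pooled peaks from rank 106 on, which the comparisons above do not use. Each of them had a q-value above 0.05, and the pooled list runs up to a q of 0.960 and includes background by design, so a weaker peak near a start is not called binding here. All tests on them were chosen only after the data had been seen, except that the gene lists and RGGTCA were fixed before, and the genes named from them were chosen after their values were seen.

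The lists of molting genes, molting-timer genes, cuticle collagens and ribosomal protein genes had a weaker peak near a start more often than other genes did. Heterochronic and molting-timer genes had 8 of 18 members with a weaker peak within 1000 bp of a start, where the share of all genes gives 1.70 (odds ratio 7.71, Fisher's exact test adjusted p = 0.00226). They were kin-20, nhr-23, myrf-1, lin-28, lin-42, lin-14, nhr-25 and lin-66. Molting genes had 9 of 31 against 2.92 (odds ratio 3.94, adjusted p = 0.00854, exact test), among them noah-1 (rank 213), myrf-2 (rank 326) and mlt-7 (rank 791). The 2 lists share 7 members, 4 of them with a weaker peak, so they are not independent. Without nhr-23, of which the strain has extra copies, 7 of 17 and 8 of 30 had a weaker peak (adjusted p = 0.00422 and 0.0272, exact tests). Cuticle collagens had 31 of 176 against 16.6 (odds ratio 2.07, adjusted p = 0.00422, exact test), with col-103, col-39, bli-1 and rol-6 the highest by signal. Ribosomal protein genes had 18 of 79 against 7.45 (odds ratio 2.85, adjusted p = 0.00326, exact test). The other 16 lists did not pass, and they include lists related to the cuticle and its shedding. Odds ratios were below 1 for astacin and ADAMTS proteases (1 of 42, 0.234, the lowest of the 20), histone genes (0.400) and genes of intestine (1 of 24, 0.417), sperm (3 of 71, 0.423) and neurons (11 of 122, 0.952). The highest of the 16 was that of furrow collagens (3 of 6, odds ratio 9.62, adjusted p = 0.0538, exact test), followed by epidermal regulators (2.96), germline genes (6 of 27, odds ratio 2.75, unadjusted p = 0.0367, exact test), heat shock genes (2.40), vacuolar ATPase genes (2.26), body muscle genes (2.02), hedgehog-related genes (1.73), fatty acid genes (1.60), patched-related genes (1.54), nuclear hormone receptors (1.37) and cuticle enzymes and apical matrix genes (6 of 56, 1.15). By circular shifts in place of Fisher's test, 6 lists passed, with nuclear hormone receptors and furrow collagens added.

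RGGTCA was in 8.70% of the weaker summit windows and 6.51% of their flanks (331 of 3805 and 484 of 7436, odds ratio 1.37, Fisher's exact test p = 3.22e-05). Summits were richer in G and C than flanks, so base composition was tested as a technical explanation. Against random windows of the same GC content the odds ratio was 1.24 (p = 0.000513, exact test), which argues against GC content as the whole cause. WGATAR, the GATA-factor site, had an odds ratio of 1.21 against the same windows (p = 1.95e-06, exact test), but against flanks it went the other way without passing (26.3% and 27.9%, odds ratio 0.925, p = 0.0851, exact test). Other properties of open regulatory DNA stay open, and no biological explanation was tested, since the design has 1 group.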

How the results depend on the processing

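Of the settings tried, those on GC content, the elt-1 peaks, nhr-23 and reproducible peaks in the hexamer screen were chosen after seeing the data. The replicate overlap kept its direction and its side of the threshold in all 5 alternatives (6.0% to 10.4%), and the count of reproducible peaks stayed within 1.5 times on ce10. Overlap of 1 bp in place of summit distance found 96.2% of reproducible peaks in replicate 1 and 98.1% in replicate 2. The promoter share fell below that of shifted positions in the stronger 52 peaks (38.5%) and was 35.2% to 52.4% with 1 replicate left out. The number of gene lists passing at reproducible peaks was 0 with a 2000 bp window, 4 with nearest genes, 0 in the stronger 52 peaks and 0 to 2 with 1 replicate left out, where replicate 1 alone passed molting genes and molting-timer genes, and 1 list, the molting-timer genes, without nhr-23. At shared strong peaks it was 1 with a 2000 bp window, 2 with nearest genes and 0 to 3 with 1 replicate left out. Lists with 1 bound member lost it and fell to an odds ratio of 0: cuticle collagens with a 500 bp window (0) and in the stronger 52 peaks (0), with 0 to 3.91 with 1 replicate left out; heat shock genes in the stronger 52 peaks (0) and with either replicate left out (0); hedgehog-related genes with 0 to 19.4 with 1 replicate left out; epidermal regulators without the elt-1 peaks (0); and nuclear hormone receptors in the stronger 34 shared strong peaks (0). The odds ratio of RGGTCA at reproducible peaks was 0.558 for TRGGTCA and 0.767 in the stronger 52 peaks. In the other 7 settings it was 1.19 to 1.96, without passing the exact test. Against windows of the same GC content it was 1.79 (p = 0.0643, exact test), and with replicate 2 alone 1.96 (p = 0.0993, exact test). At shared strong peaks it was 0.715 with 50 bp windows, 3.30 with 150 bp windows and 0 for TRGGTCA. There the other 6 settings gave 1.23 to 2.69, also without passing. The hexamer screen gave 10 more frequent hexamers against windows of the same GC content, 3 without the peaks within 20 kb of elt-1, 29 at reproducible peaks and 23 at those against windows of the same GC content, while less frequent hexamers numbered 1 in the screen as planned and 0, 1, 18 and 3 in these settings. The mean percentile of unc-119 was 17.1 with 10 kb windows. The cause was not tested in any of these, beyond the smaller numbers of peaks that the stronger peaks and the left-out loci give. No paired analysis was possible because the design has 1 group. Depth is unknown, so what it limits cannot be given.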

Other observations

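The tests in this part were chosen after the result was seen. The percentiles at nhr-23 were planned as a check of the strain, but their use on a mislabelled library was not.

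WGATAR, the GATA-factor site, was within 75 bp of 47 of 105 reproducible summits (44.8%) and in 28.8% of flanks (odds ratio 2.00, Fisher's exact test p = 0.00567), and in the stronger 52 peaks the odds ratio was 4.23. Without the peaks within 20 kb of elt-1 the odds ratio was 1.85 (p = 0.0195, exact test), so the pattern did not rest on that locus alone. Leaving out 5 of 105 peaks could change the ratio only a little. Summits had more G and C than flanks (44.7% and 37.4%), which would make an AT-rich site rarer at summits. Windows of the same GC content as summits held WGATAR in 23.6%, fewer than flanks did, which gave an odds ratio of 2.62. Matching could only raise the ratio, so 2.62 is no further test. The excess over flanks itself argues against GC content as its cause, while other features of base composition were not tested. The 105 strongest peaks of replicate 2 alone gave 2.87 (p = 2.89e-05, exact test) and those of replicate 1 alone 1.26 (p = 0.370, exact test), a difference that was not tested, and windows at starts of unbound genes as control gave 1.77 (p = 0.0644, exact test). Windows of 150 bp either side also gave no call (59.0% of summits and 50.5% of flanks, odds ratio 1.41, p = 0.185, exact test), while those of 50 bp gave 2.62 (p = 0.000348, exact test). A mislabelled library or one mixed with material from another strain cannot be told apart from NHR-23 at sites of a GATA factor. The 20 kb window of nhr-23 lay at percentile 99.5 in replicate 1 and 73.9 in replicate 2 (89.2 with 10 kb and 90.9 with 40 kb). The molting lists and RGGTCA at the weaker peaks go the way the label says without excluding a mixture. They are not particular to the label, since other results at those peaks differ. Ribosomal protein genes passed there too (odds ratio 2.85), and astacin and ADAMTS proteases went the other way without passing (0.234). WGATAR was also more frequent there against windows of the same GC content (1.21), but not against flanks (0.925, p = 0.0851, exact test). No biological explanation was tested, as the design has 1 group.

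The cluster of peaks at elt-1 might come from extra copies of that region, which would raise all peaks in it alike. In the outer part, 5 to 20 kb from the middle of the gene, the number of peaks lay at percentile 69.2 in replicate 1 and 96.9 in replicate 2. By number, the replicates thus differ and decide nothing. At nhr-23, which is carried in extra copies, the same outer part lay at percentile 98.1 in replicate 1 and 25.1 in replicate 2. How far those copies reach is not given here, and peak number may miss a gain. Signals were not alike: outer peaks reached 30.8 in replicate 1 and 30.2 in replicate 2, where the main peak had 216.1 and 338.3. In the pooled list outer peaks had 24.4 to 40.7 and the main peak 557.7. These values argue against a flat gain of the whole window as the only cause of the main peak. A gain of a shorter stretch, or a gain together with binding, cannot be told apart from other causes. No test was made that separates a gain from binding at the main peak.

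By rank in the pooled list, the share of windows with WGATAR was 44.8% at ranks 1 to 105, 29.9% at 106 to 500, 28.6% at 501 to 1000, 26.0% at 1001 to 2000 and 25.1% at 2001 to 3910, against 20.2% to 23.8% in windows of the same GC content. Against flanks, the control used at the reproducible peaks, the peaks from rank 106 on went the other way without passing (26.3% of summits and 27.9% of flanks, odds ratio 0.925, Fisher's exact test p = 0.0851), while against windows of the same GC content they held it more often (odds ratio 1.21, p = 1.95e-06, exact test). At those peaks RGGTCA gave 1.37 against flanks and 1.24 against windows of the same GC content. It showed 13.3%, 11.1%, 7.80%, 8.40% and 8.59% over the same ranks, against 6.89% to 7.90%. The window of lin-42 held 31 peaks in replicate 1 and 20 in replicate 2, at the 99.9th percentile in each, and that of elt-1 20 and 18, at the 96.2nd and 99.8th.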
